A study of Mus musculus with 12 samples.

How the data were processed

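Poly(A)-selected RNA of mouse embryonic stem cells was sequenced in 12 libraries that fall into 4 groups of 3. The cells are of the E14 line and carry RACK1 fused to an auxin-inducible degron, together with the auxin receptor TIR1 fused to the small-subunit ribosomal protein RPS26. Auxin (indole-3-acetic acid, IAA) then brings the TIR1 on the ribosome to the degron, so that RACK1 protein, itself a component of the small ribosomal subunit, is destroyed there. In the first comparison cells were kept in IAA or in the solvent DMSO for 5 days. In the second, cells that had received IAA for 5 days were compared with a DMSO control 10 days after IAA was withdrawn. RNA was extracted with Trizol and made into TruSeq libraries, per the labels. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

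The authors' 2 files are tables of their own comparisons, 1 per time, with 1 transcript per gene and no columns of single libraries. Their columns are those of the limma package's result table, per the file headers. The authors gave the log2 fold change and the mean log2 CPM over the 6 libraries of each comparison. The deposited moderated t statistic and log-odds are scores without a unit. The deposited p-value of each gene stands beside its Benjamini-Hochberg (BH) adjusted value, and BH recomputed over the rows differed from it by at most 4.86e-05. The authors also deposited the length of each transcript part, the GC content as a fraction, the number of upstream AUGs and the folding energy of the untranslated regions as a score whose unit is not named. The aligner, the counting program, the genome build and the limma version used upstream are not given in the sources used here.

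The values themselves show part of that processing. In the 5-day table, 552 genes shared the mean log2 CPM expected of genes with 1 read in 1 library. Their folds took 6 values, 3 above 0 and 3 below, as 6 libraries of different depth would give. Genes with 2 reads in 1 library lay 0.123 higher, which is log2(5/3)/6 for a prior count of 0.5, and the largest deviation from this step was 3.78e-10 over both tables. From this lattice the geometric mean of the effective library sizes was 23.3M reads at 5 days and 21.2M at 10 days. The depth of single libraries was not recoverable. The t statistics had 13.4 degrees of freedom at 5 days and 15.2 at 10 days, more than the 4 that 6 libraries in 2 groups leave, which a variance shrunken across genes gives.

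The standard error (SE) given beside each fold is the fold divided by its t, and so is the moderated SE implied by the authors' deposited table. Its median over genes above a mean log2 CPM of 3 was 0.077 at 5 days and 0.115 at 10 days. At or below a mean log2 CPM of 0 it was 0.738 and 0.883, so folds of rare transcripts are poorly resolved.

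The headers do not say which group a positive fold favours, and it was read as higher in cells given IAA. A check used the difference of mean log2 CPM between the tables, to which a 5-day change contributes 0.5 of its log2 fold if the reading is right and -0.5 if it is reversed. Over 4319 genes called at 5 days the slope was 0.685 ± 0.0143 (SE). The check rests on the levels of 2 tables that were normalized separately, and its SE treats genes as independent. It also takes the DMSO controls of the 2 times as alike. On this reading they differed in formative and primed pluripotency genes, a median of 0.98 log2 CPM higher in the 5-day control, and the slope lay above 0.5.

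There were 18765 genes with values at 5 days and 18712 at 10 days, each with 1 emptied row besides. At each time 27 symbols had been turned into calendar dates by a spreadsheet. They were restored through the gene IDs and a table of gene names, which matched 18749 and 18696 IDs. Of the versioned transcript IDs, 97.5% at 5 days and 97.6% at 10 days were in GENCODE M21, with the same length for all that matched. Coordinates are from that annotation on GRCm38, 1-based, and the build the authors mapped to may differ.

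The plan made before the data were examined was a count test, with limma on log values as its fallback. Neither could be refitted without library values, so the authors' limma results at a BH adjusted p under 0.05 are the main result. For the same reason no count model was run, and DESeq2 and edgeR were not used. The change at 5 days was set against that at 10 days by the planned fallback, a z test of the difference of the 2 log2 folds with their implied SEs, BH adjusted over the 18120 genes in both tables. The 2 comparisons share no control library.

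The study of gene groups used 36 lists of textbook members fixed before the data were examined. Lists were tested with limma's cameraPR on the z-converted t statistics, two-sided, BH adjusted over the 36 lists, with a preset inter-gene correlation of 0.01. The estimated correlation and the rotation test need library values and could not be run. A preset correlation of 0.05 was used in their place, chosen after seeing the data. Tests are against the other genes in the table.

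Genes were named by a rule fixed before the data were examined. It takes the tagged genes Rack1 and Rps26. It takes the 10 largest rises and 10 largest falls with an adjusted p under 0.05 and a mean log2 CPM of at least 1, leaving out predicted-gene names. From each list it takes up to 4 members of smallest p where the list passes or at least 3 members are called, and otherwise up to 2. The part on genes called at both times named none, as there were 0, and its planned overlap test was not run. It also takes the 6 smallest p-values of the difference between the times. The part of the rule that asks for no overlap between single libraries could not be applied.

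Alternatives added after seeing the data were a mean log2 CPM above 0, folds with the median of genes above a mean log2 CPM of 3 set to 0, and removal of trends. Further ones were an adjusted p under 0.01, a test against a 1.2-fold change and a t distribution for the difference between the times. Trends of the log2 fold with log2 transcript length and GC fraction, and in a further setting mean expression, were removed by regression on B-splines with 5 degrees of freedom fitted above a mean log2 CPM of 0. The least-squares fit set the mean of the fitted genes to their former median, so with skewed folds every fold was also shifted.

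The difference test, the list test, the depth estimate and the trend removal were tested on simulated data. The difference test, over 18120 genes with the real SEs, recovered 38.0%, 80.2% and 96.9% of changes of 0.5, 1 and 2 on the log2 scale, with 4.61% of calls false. That simulation took the SEs as known exactly, so its false share leaves out the error of the estimated SEs. The list test recovered 95.2% of lists shifted by 1 SD and called 0.222% of unshifted lists. Its simulated genes were drawn independently, so these rates do not hold for list members that vary together. The depth estimate returned 23.1M reads for a true 23.1M. Trend removal took a simulated length correlation from 0.495 to 0.000973. The data for depth and trend were simulated in the form each step assumes, so these results check only the code.

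Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, patsy 1.0.2 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.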

Results

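Ribosomes of these mouse embryonic stem cells could be stripped of RACK1, a small-subunit protein, by adding auxin (IAA). Poly(A) RNA was measured after 5 days in IAA or DMSO, and again 10 days after IAA was withdrawn from treated cells, with a DMSO control at each time and 3 libraries in each of the 4 groups. The effective depth was about 23.3M reads per library at 5 days and 21.2M reads at 10 days, as geometric means. The first comparison asks which transcripts change over 5 days in IAA, and the second whether they still differ 10 days after withdrawal. Values are folds of IAA-treated over DMSO cells on the log2 scale, with the standard error implied by the authors' deposited table. Positive values are read as higher with IAA, a reading that the headers do not state. Across genes called at 5 days the difference of mean level between the tables followed the 5-day fold with a slope of 0.685 ± 0.0143 (SE), where this reading gives 0.5 and the reverse -0.5. Those values assume that the DMSO controls of the 2 times are alike, and the SE treats genes as independent. With positive read as higher with IAA, the controls differed in formative and primed pluripotency genes, a median of 0.98 log2 CPM higher at 5 days. Control levels were derived from each gene's mean and fold, so this difference itself rests on that reading.

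Of the tagged genes, Rack1 RNA was slightly lower at 5 days and Rps26 RNA did not pass at either time. Rack1 (ENSMUST00000020640.7, chromosome 11, 48800360 to 48806434, plus strand, 8 exons, GENCODE M21 on GRCm38) had a log2 fold of -0.17 ± 0.04 (SE) at 5 days in the authors' deposited table, with a limma BH adjusted p of 0.0051. At 10 days the authors' deposited table gave Rack1 -0.06 ± 0.09 (adjusted p = 0.912). Rps26 (ENSMUST00000026420.6, chromosome 10, 128624537 to 128626747, minus strand, 4 exons), which carries TIR1, had -0.05 ± 0.04 at 5 days (adjusted p = 0.393) and -0.22 ± 0.11 at 10 days (adjusted p = 0.901) in the authors' deposited table. The data hold RNA, so neither the loss of RACK1 protein nor its return was measured here. With length, GC and expression trends removed Rack1 stood at -0.02 at 5 days and no longer passed.

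After 5 days of IAA, 4789 of 18765 genes (25.5%) passed a limma BH adjusted p of 0.05 in the authors' deposited table, 2524 higher and 2265 lower. As lists, with members that did not pass in each, formative and primed pluripotency, p53 targets, Nodal and BMP targets, and fibroblast feeder markers tested higher. Naive pluripotency, the 2-cell-like state, oxidative phosphorylation, DNA replication, the ATF4 response and replication-dependent histones tested lower. All of these lists kept their calls under every alternative tried, though none of the alternatives could use values of single libraries. Changes of at least 1 on the log2 scale were mostly rises, 835 against 201 falls in the authors' deposited table. With the trend of folds on transcript length and GC removed, which also shifted the centre of the folds, 1993 genes were higher and 2869 lower. With the median fold set to 0 there were 2775 and 1960, so the balance of directions depends on scaling.

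Among called genes with a mean log2 CPM of at least 1 and no predicted-gene name, the largest rise was in Fgf5, a growth factor gene of the primed epiblast. It rose by 4.82 ± 0.59 (SE) in the authors' deposited table (limma adjusted p = 7.58e-05, chromosome 5, 98254184 to 98277030, GRCm38). Its mean level was only 1.19 log2 CPM, so its fold rests on few reads in DMSO cells. In the authors' deposited table Sema6a, a transmembrane semaphorin, rose by 3.28 ± 0.28, Zfp608 by 3.04 ± 0.31 and Car4, a carbonic anhydrase, by 2.92 ± 0.18. Mmp25, a membrane-anchored metalloproteinase, rose by 2.61 ± 0.23, again in the authors' deposited table. Enpp2, which makes lysophosphatidic acid, Psmb8, an immunoproteasome subunit, and Kcnj3, a potassium channel subunit, rose by 2.43 ± 0.27, 2.39 ± 0.24 and 2.38 ± 0.24 in the authors' deposited table. The smallest p of the whole table was that of Kif1a, an axonal kinesin, which rose by 2.18 ± 0.10 (adjusted p = 5.28e-08, chromosome 1, 93015464 to 93101822) in the authors' deposited table.

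Among falls within the same limits on level and name, Slc11a1, a metal transporter of phagocytes, led with -2.07 ± 0.35 in the authors' deposited table (limma adjusted p = 0.000818). Inhbb, the beta B subunit of activins and inhibins, stood at -1.89 ± 0.14, Serpinb6c at -1.77 ± 0.24 and the septin gene Sept1 at -1.66 ± 0.17 in the authors' deposited table. Mapt, which encodes tau, had -1.64 ± 0.31, the Ras-like GTPase gene Mras -1.53 ± 0.08 and the galectin gene Lgals3 -1.52 ± 0.11 in the authors' deposited table. Myo1f, an unconventional myosin, had -1.48 ± 0.10 in the authors' deposited table, where Gna14, a G protein subunit, was 2.83-fold lower (adjusted p = 1.39e-05). Tbx3, a transcription factor of naive pluripotency, completed the 10 largest falls with -1.55 ± 0.19 in the authors' deposited table. All of these rises and falls kept their call with the median set to 0 and with length and GC trends removed.

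The lists of formative and naive pluripotency moved in opposite directions. RNA was pooled over cells, so a change in all cells cannot be told from a change in some of them. Of 19 measured genes of formative and primed pluripotency 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold of 0.88 and a list test adjusted p of 3.42e-14. In the authors' deposited table Pou3f1 rose by 2.39 ± 0.13, Pim2 by 2.18 ± 0.12, Otx2 by 1.91 ± 0.10 and Sox4 by 0.88 ± 0.07. Of 26 genes of naive pluripotency 20 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.55 (list test adjusted p = 6.59e-13). Tfcp2l1 had -1.13 ± 0.08, Tcl1 -0.93 ± 0.09, Nr0b1 -0.84 ± 0.08 and Nanog -0.74 ± 0.06 in the authors' deposited table. Of 25 genes of the 2-cell-like state, 11 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.67, list test adjusted p = 3.50e-06). Zscan4f (-0.94 ± 0.10), Zscan4a (-0.91 ± 0.12) and Zscan4c (-0.76 ± 0.10) are near-identical paralogs in the authors' deposited table, so reads may be split between them. The list counts such paralogs as separate genes, so its count and p may rest on fewer independent signals.

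Signalling and stress lists also moved. Of 36 p53 targets 19 rose and 1 fell (20 and 2 adjusted over the list alone, median 0.39, list test adjusted p = 2.43e-08). The authors' deposited table gave Phlda3 1.33 ± 0.08, Plk2 1.30 ± 0.11, the pro-apoptotic gene Bbc3 0.92 ± 0.08 and Trp53inp1 0.87 ± 0.07. Of 19 Nodal and BMP targets 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.35, list test adjusted p = 0.00119). The Nodal antagonist genes Lefty1 and Lefty2 rose by 1.26 ± 0.06 and 0.82 ± 0.07 in the authors' deposited table. Of 38 genes of the ATF4 integrated stress response 19 fell and 2 rose (22 and 3 adjusted over the list alone, median -0.21, list test adjusted p = 2.10e-06). They include Cth (-0.71 ± 0.07), the amino acid transporter gene Slc7a1 (-0.68 ± 0.06) and the serine synthesis gene Psat1 (-0.42 ± 0.04) in the authors' deposited table. Of 38 imprinted genes 13 rose and 4 fell (14 and 4 adjusted over the list alone, median 0.25, list test adjusted p = 0.0112, and 0.104 with a preset correlation of 0.05, its alternatives spanning 0.00486 to 0.104). Dlk1 rose by 1.13 ± 0.16, Peg10 by 0.83 ± 0.10 and Snrpn by 0.62 ± 0.08 in the authors' deposited table.

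The lists of oxidative phosphorylation, the proteasome, DNA replication and G2/M tested lower, by small amounts. All 76 nuclear genes of oxidative phosphorylation had folds below 0, and 68 passed (72 adjusted over the list alone, median -0.31, list test adjusted p = 1.61e-27). Among them the authors' deposited table gave Atp5g1 -0.56 ± 0.06, Atp5j2 -0.54 ± 0.06, Cox5a -0.53 ± 0.06 and Sdhb -0.47 ± 0.05. Of 40 proteasome and ubiquitin genes 30 fell and 2 rose (33 and 2 adjusted over the list alone, median -0.20, list test adjusted p = 7.60e-11), Psmd13 at -0.35 ± 0.05 in the authors' deposited table. Of 41 genes of DNA replication and G1/S 25 fell and 0 rose (29 and 1 adjusted over the list alone, median -0.20, list test adjusted p = 1.61e-10). In the authors' deposited table Ccnd3, a D-type cyclin, had -0.57 ± 0.06, the origin recognition gene Orc1 -0.49 ± 0.07 and the helicase subunit gene Mcm6 -0.33 ± 0.04. Of 30 G2/M genes 7 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.11, list test adjusted p = 0.000519), with Ccnb2 at -0.35 ± 0.06 in the authors' deposited table. With length, GC and expression trends removed the proteasome and G2/M lists no longer passed (adjusted p = 0.314 and 0.267), over alternatives of 4.01e-10 to 0.314 and 0.000124 to 0.267.

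Lists of ribosomal proteins, the mitochondrial genome and translation factors tested lower too, and here transcript length enters. Of 79 cytosolic ribosomal protein genes 61 fell and 0 rose (67 and 0 adjusted over the list alone), with a median of -0.21, Rpl36a at -0.45 ± 0.06 and Rps14 at -0.29 ± 0.05 in the authors' deposited table. The list test gave an adjusted p of 4.30e-19, which became 0.152 with length and GC trends removed. With the expression trend removed as well the list's direction turned to higher (adjusted p = 0.0138), the alternatives spanning 5.44e-18 to 0.152. Of 76 mitochondrial ribosomal protein genes 23 fell and 1 rose (26 and 1 adjusted over the list alone, median -0.14, list test adjusted p = 3.14e-06, alternatives 8.72e-07 to 0.987), with Mrpl24 at -0.40 ± 0.07 in the authors' deposited table. Of 13 genes of the mitochondrial genome 10 fell (11 adjusted over the list alone, median -0.26, list test adjusted p = 2.91e-07), mt-Cytb at -0.40 ± 0.03 in the authors' deposited table. That call was lost with length and GC trends removed (adjusted p = 0.897), and with the expression trend removed too the direction turned to higher (adjusted p = 0.0922), the alternatives spanning 1.25e-05 to 0.897. Of 48 translation factors 23 fell and 4 rose (26 and 4 adjusted over the list alone, median -0.13, list test adjusted p = 1.33e-05), Eif4b at -0.36 ± 0.04 in the authors' deposited table. Their call was lost with length, GC and expression trends removed (adjusted p = 0.391, alternatives 4.12e-05 to 0.391). Replication-dependent histone genes, whose RNAs lack poly(A) tails, fell as a list (3 of 27 passing, and 3 adjusted over the list alone, median -0.56, list test adjusted p = 0.000231), with Hist1h1c at -0.68 ± 0.17 in the authors' deposited table.

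Other lists passed less firmly. Of 25 genes of cholesterol synthesis 10 fell and 2 rose (12 and 3 adjusted over the list alone), led by Acat2 at -0.48 ± 0.06 in the authors' deposited table. NRF2 targets had 10 falls and 3 rises among 27 (12 and 3 adjusted over the list alone), with Nqo1 at -0.98 ± 0.12 in the authors' deposited table. Lysosome and autophagy genes had 12 falls and 3 rises among 34 (12 and 3 adjusted over the list alone), with Gabarapl2 at -0.61 ± 0.06 in the authors' deposited table. Cytosolic heat shock genes had 8 falls and 3 rises among 20 (8 and 3 adjusted over the list alone), with Hspb1 at -0.71 ± 0.05 in the authors' deposited table. The list tests of these 4 gave adjusted p-values of 0.0107, 0.0154, 0.0284 and 0.0344. With a preset correlation of 0.05 none of the 4 passed (adjusted p = 0.0748, 0.10, 0.149 and 0.125). Over their alternatives the adjusted p-values spanned 0.00354 to 0.0748, 0.0245 to 0.689, 0.0245 to 0.267 and 0.0330 to 0.317. The 16 lists that passed besides these and imprinted genes also passed at that correlation.

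Markers of fibroblast feeder cells, which many stem cell cultures contain, rose as a list in IAA: 9 of 23 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.43, list test adjusted p = 0.00101). Among the 9 were Lox (4.75 ± 0.64), Mmp2 (1.14 ± 0.10), Ctgf (1.03 ± 0.13) and the collagen genes Col6a1 (1.94 ± 0.45) and Col6a2 (1.57 ± 0.32) in the authors' deposited table. Lox lay below the mean log2 CPM of 1 required of the largest rises, so its fold rests on few reads. Of the other collagens none passed, and Col5a1 had 0.09 ± 0.08 in the authors' deposited table. Levels derived from the mean and fold there were 1.44 log2 CPM in IAA and 1.55 in DMSO for Col1a1. Col1a2 stood at 0.09 and -0.34, and Col3a1, near the detection floor, at -3.41 and -3.33.

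The remaining 15 lists did not pass at 5 days, with calls in both directions in each. Ribosome quality control had 9 falls and 2 rises among 32 (10 and 3 adjusted over the list alone, list test adjusted p = 0.0789, but 0.00169 as lower with length and GC trends removed, alternatives 0.00169 to 0.256), with Map3k20, the ribosome collision kinase, at 1.12 ± 0.18 and Zc3h12a at -0.91 ± 0.14 in the authors' deposited table. Ribosome biogenesis had 4 rises and 3 falls among 55 (3 and 3 adjusted over the list alone, adjusted p = 0.649), Polr1c at -0.38 ± 0.05 in the authors' deposited table. Primitive streak and mesendoderm had 5 rises and 1 fall among 20 (5 and 1 adjusted over the list alone, adjusted p = 0.162), Fgf8 at 1.68 ± 0.34 in the authors' deposited table. Primitive endoderm had 6 rises and 3 falls among 22 (7 and 4 adjusted over the list alone, adjusted p = 0.616), Dab2 at 1.79 ± 0.23 and Lama1 at -0.97 ± 0.07 in the authors' deposited table. Neuroectoderm had 4 rises and 3 falls among 23 (4 and 3 adjusted over the list alone, adjusted p = 0.936, the test pointing lower and the median, 0.21, higher), Nes at 1.77 ± 0.21 and Stmn2 at -0.97 ± 0.05 in the authors' deposited table. Trophectoderm had 2 rises and 2 falls among 17 (2 and 3 adjusted over the list alone, adjusted p = 0.616), and germ line 3 rises and 4 falls among 22 (4 and 5 adjusted over the list alone, adjusted p = 0.248). ERK immediate early and feedback genes had 7 rises and 4 falls among 22 (7 and 4 adjusted over the list alone, adjusted p = 0.348), Jun at 1.36 ± 0.14 and Spry4 at -0.63 ± 0.08 in the authors' deposited table. Canonical WNT targets had 5 rises and 2 falls among 18 (5 and 2 adjusted over the list alone, adjusted p = 0.433). Actin and focal adhesion genes had 11 rises and 8 falls among 35 (13 and 9 adjusted over the list alone, adjusted p = 0.283), Zyx at 0.98 ± 0.10 in the authors' deposited table. Interferon-stimulated genes had 4 rises and 7 falls among 24 (4 and 8 adjusted over the list alone, adjusted p = 0.969, with a median of -0.14 and a mean of 0.35). Glycolysis and hypoxia had 3 rises and 8 falls among 35 (3 and 8 adjusted over the list alone, adjusted p = 0.162), and the ER unfolded protein response 1 rise and 5 falls among 25 (1 and 5 adjusted over the list alone, adjusted p = 0.246). Genes of PKC and RACK1 partners had 3 rises and 3 falls among 28 (3 and 3 adjusted over the list alone, adjusted p = 0.513). Aryl hydrocarbon receptor targets, included since auxin is an indole, had 2 rises and 2 falls among 13 (2 and 2 adjusted over the list alone, adjusted p = 0.875).

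**Figure D1:**
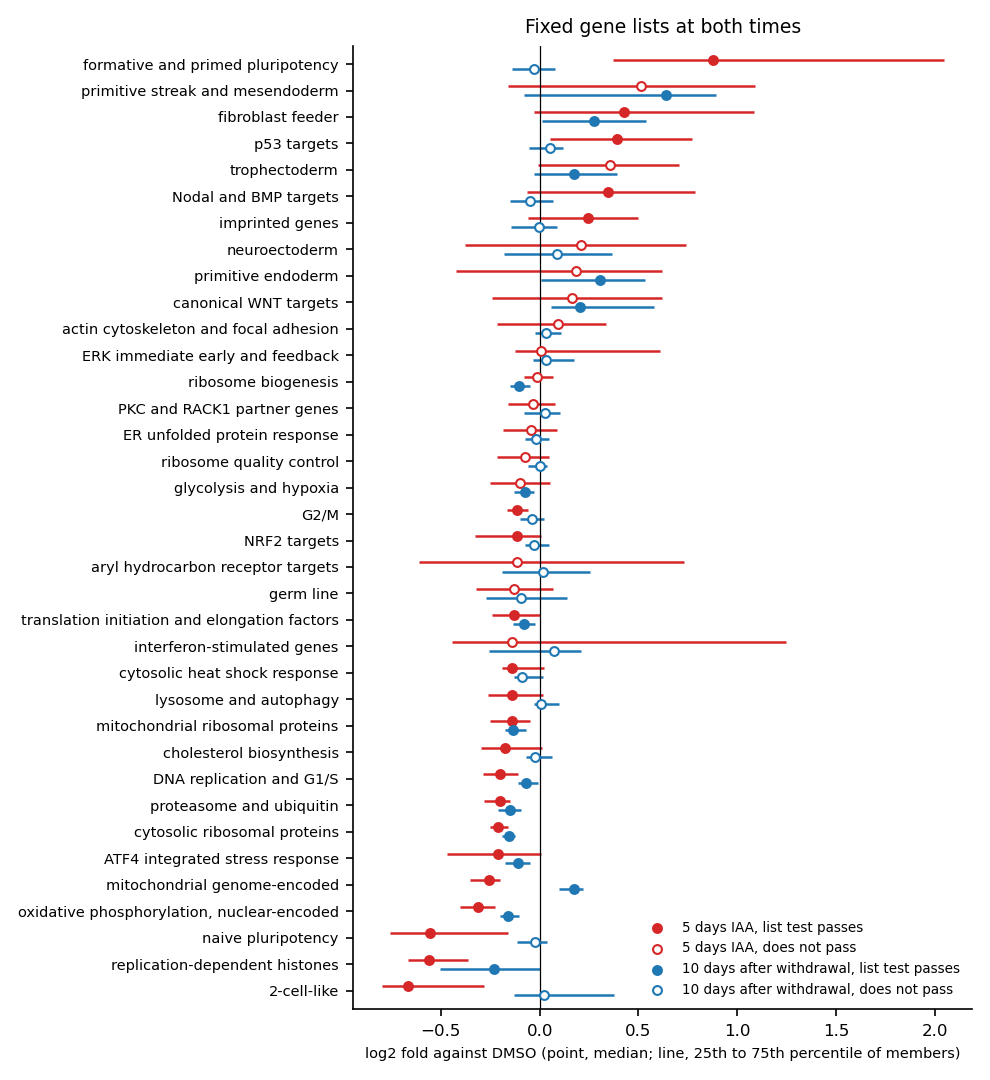
Log2 fold of IAA-treated over DMSO cells (horizontal axis) for the members of each fixed gene list, at 5 days in red and 10 days after withdrawal in blue; points are medians, lines run from the 25th to the 75th percentile, and filled points mark lists that pass the list test. The formative list stands at 0.88 at 5 days and -0.03 at 10 days, and the naive list at -0.55 and -0.02.

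At 10 days after IAA was withdrawn, no gene stood apart between the cells that had received it and their DMSO control. Of 18712 genes, 0 passed limma's BH adjusted p of 0.05 in the authors' deposited table, and 805 had an unadjusted p under 0.05 where chance alone gives 935.6. The smallest adjusted p in the authors' deposited table was 0.822. The spread was wider than at 5 days, with a median SE of 0.115 against 0.077 above a mean log2 CPM of 3. Had the 5-day folds of called genes persisted in full, a simulation with the 10-day SEs called a mean of 2361 of them (2280 to 2459 over 100 draws). It called 152.7 had 0.5 of each log2 fold persisted. The simulation took folds selected for passing at 5 days as the true changes and drew genes independently. Both means may therefore be too high and the range too narrow.

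None of the marked changes of day 5 passed at 10 days. Fgf5 stood at -0.01 ± 1.14 in the authors' deposited table, near the detection floor at a mean of -3.34 log2 CPM, so a large change in either direction stays open. Pou3f1 stood at 0.16 ± 0.16, Otx2 at -0.33 ± 0.22 and Pim2 at -0.18 ± 0.15 in the authors' deposited table, with none passing. On the naive side the authors' deposited table gave Tbx3 0.15 ± 0.09, Tfcp2l1 0.20 ± 0.12, Nanog -0.12 ± 0.09 and Tcl1 -0.24 ± 0.10, again with none passing. Of 19 formative genes 8 had folds above 0 and 11 below (list test adjusted p = 0.771, with a median of -0.03 and a mean of 0.08), and of 26 naive genes 10 and 16 (adjusted p = 0.363). The 36 p53 targets had a median of 0.05 (list test adjusted p = 0.235, but 0.0494 as higher with length, GC and expression trends removed, alternatives 0.0494 to 0.533), Btg2 at 0.24 ± 0.13 in the authors' deposited table.

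Although no gene passed, 16 of the 36 lists did, with small shifts shared by many members. Cytosolic ribosomal protein genes had 75 of 79 folds below 0 (median -0.15, list test adjusted p = 2.95e-17), oxidative phosphorylation 74 of 76 (median -0.16, 2.91e-13) and mitochondrial ribosomal proteins 68 of 76 (median -0.14, 1.63e-09), all adjusted p-values from limma's cameraPR. Proteasome genes followed with 37 of 40 folds below 0 (median -0.15, adjusted p = 1.73e-09) and ribosome biogenesis with 51 of 55 (median -0.10, adjusted p = 9.21e-07). Translation factors (median -0.08, adjusted p = 6.28e-05), ATF4 targets (-0.11, 0.000208), glycolysis (-0.08, 0.00186), DNA replication (-0.07, 0.00193) and histones (-0.23, 0.0385) were lower as well. In none of these 10 lists did a member pass when adjusted over the list alone. With length, GC and expression trends removed, mitochondrial ribosomal proteins (adjusted p = 0.0338), ribosome biogenesis (0.00436) and ATF4 targets still passed as lower. Lost in that setting were cytosolic ribosomal proteins (adjusted p = 0.437, alternatives from 2.68e-17), oxidative phosphorylation (0.356, from 1.09e-13), the proteasome (0.109, from 3.11e-09) and translation factors (0.243, from 4.76e-05). Glycolysis (adjusted p = 0.107, alternatives from 0.000970), DNA replication (0.205, from 0.000778) and histones (0.0727, from 0.0225) were lost there too.

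Higher at 10 days were the 13 genes of the mitochondrial genome, 12 with folds above 0 (median 0.17, list test adjusted p = 0.00649). Their 5-day direction was lower, but not with length, GC and expression trends removed, where both times pointed higher (adjusted p = 0.0922 and 2.87e-09). Fibroblast markers were higher too, with 17 of 22 folds above 0 (median 0.28, list test adjusted p = 0.000416) and 2 members passing when adjusted over the list alone, Thbs1 at 0.95 ± 0.23 and Acta2 at 0.94 ± 0.27 in the authors' deposited table. Here Col1a1 stood at 1.59 log2 CPM in cells after IAA and 0.71 in DMSO, and Col1a2 at 0.56 and -0.76. These levels were derived from the mean and fold in the authors' deposited table. Neither collagen gene passed when adjusted over the list alone. With these markers moved the lists of WNT targets (median 0.20, adjusted p = 0.00298), primitive endoderm (0.30, 0.00436), trophectoderm (0.17, 0.0161) and primitive streak (0.64, 0.0385), all with 0 members passing when adjusted over the list alone. In the authors' deposited table Col4a1, a basement membrane collagen, had 0.38 ± 0.14, Krt18 0.35 ± 0.14 and the WNT feedback gene Nkd1 0.58 ± 0.25, none of them passing. With a preset correlation of 0.05 the trophectoderm, primitive streak and histone lists no longer passed (adjusted p = 0.0686, 0.133 and 0.173), over alternatives of 0.00339 to 0.0686, 0.0117 to 0.636 and 0.0225 to 0.256. Primitive endoderm did not pass with length, GC and expression trends removed (adjusted p = 0.0660, alternatives from 0.00749), nor did the primitive streak list (0.0713). The 17 other lists not named for this time had adjusted p-values of 0.111 or more, although lysosome and autophagy passed as higher with length, GC and expression trends removed (0.0203, alternatives 0.0203 to 0.635). Among them 1 member, Lefty2 of the Nodal list at -0.46 ± 0.12 in the authors' deposited table, passed when adjusted over the list alone.

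Set directly against each other, the changes of the 2 times differed for 1887 of 18120 genes (z test, BH adjusted p under 0.05), 1009 with a higher value at 5 days and 878 with a lower one. That balance turned to 874 and 1088 with length and GC trends removed, and to 931 and 1031 with the expression trend removed too. Trend removal also shifted the centre of the folds, so this turn does not measure the trends alone. The z test takes the SEs as known, and with a t distribution 1257 genes differed. Of the 4772 genes called at 5 days and measured at both times, 1685 (35.3%) were among them. For 3187 of these 4772 genes the 95% interval of the 10-day fold excluded the 5-day fold, and for 1303 it lay below 0.5 of that log2 fold, so a partial change is not excluded for most. This takes no account of the error of the 5-day fold, on which the genes were selected. Genes that had risen by 1 or more had a median log2 fold of 1.58 at 5 days and 0.15 at 10 days, and those that had fallen by as much -1.41 and 0.03. The sign was shared by 2951 of the 4772 (61.8%), and 0 genes were called at both times, so no overlap test was run.

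The difference was clearest for Pim2, which was 2.36 higher at 5 days than at 10 on the log2 scale (BH adjusted p = 1.33e-29), and for the tight junction gene Cldn6, which was 1.80 higher (4.97e-30). Kif1a (1.91, adjusted p = 5.55e-25) and Pou3f1 (2.23, 7.86e-23) were higher at 5 days in the same test. Inhbb (-2.03, adjusted p = 7.86e-23) and the actin nucleator gene Cobl (-1.48, 1.72e-22) were lower at 5 days. With a t distribution the unadjusted p of these 6 genes ran from 1.19e-12 for Pim2 to 2.74e-11 for Pou3f1. In the authors' deposited table Cldn6 had 1.71 ± 0.08 at 5 days and -0.09 ± 0.13 at 10 days, and Cobl -1.33 ± 0.10 and 0.15 ± 0.10.

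**Figure D2:**
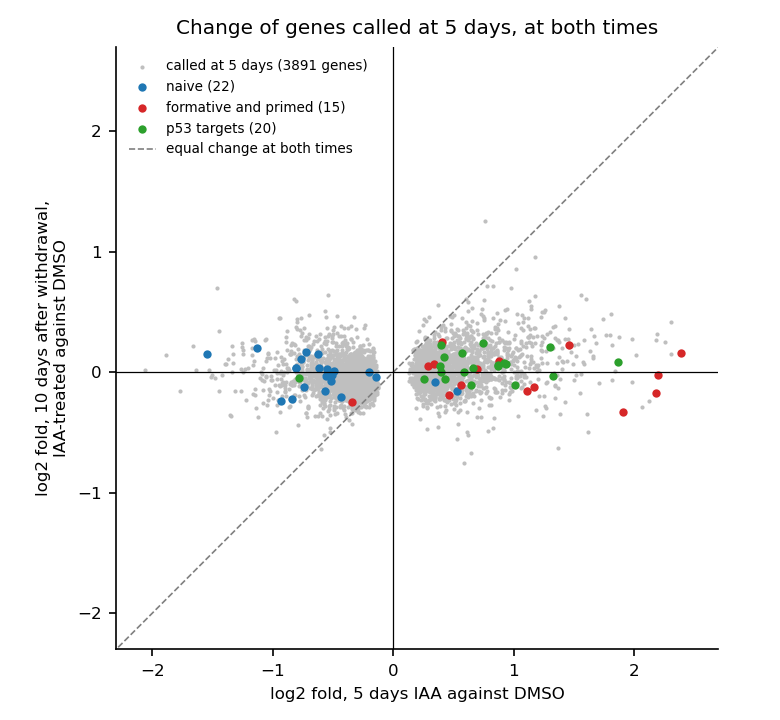
Log2 fold at 5 days (horizontal axis) against log2 fold 10 days after withdrawal (vertical axis), for 3891 genes called at 5 days with a mean log2 CPM of at least 1 at both times; colours mark called members of 3 fixed lists and the dashed line equal change. Folds spread from -2.07 to 2.39 at 5 days and from -0.76 to 1.25 at 10 days.

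Folds followed transcript length at both times. Above a mean log2 CPM of 0, Spearman's rho of the log2 fold with length across genes, which are not independent replicates, was 0.203 at 5 days and 0.411 at 10 days. The shortest 10% of transcripts had a median log2 fold of -0.17 at 5 days and -0.12 at 10 days, and the longest 10% 0.08 and 0.13. Cytosolic ribosomal protein genes, at a median of 799 nt, and oxidative phosphorylation genes, at 870 nt, have medians within the shortest 10%.

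**Figure D3:**
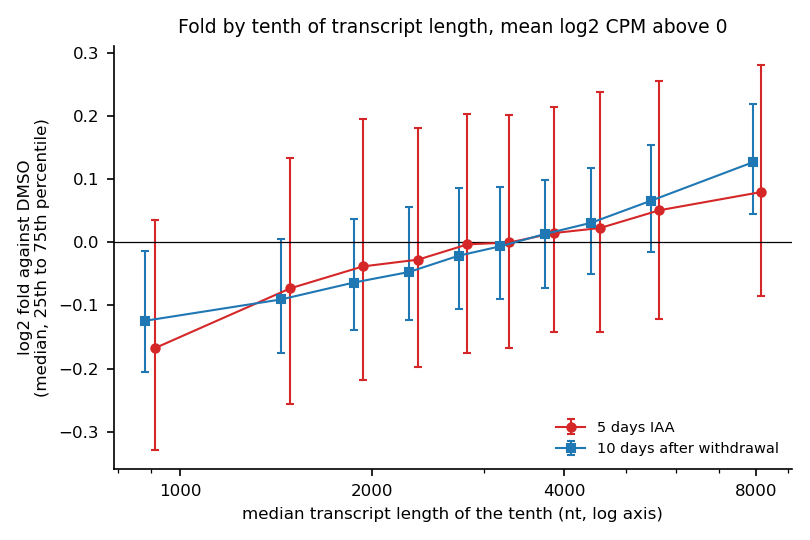
Median log2 fold (vertical axis) of genes in 10 equal groups by transcript length (horizontal axis, nt, log scale), 5 days in red circles and 10 days after withdrawal in blue squares; bars run from the 25th to the 75th percentile. Medians climb from -0.17 to 0.08 at 5 days and from -0.12 to 0.13 at 10 days.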

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

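The difference test between the times was the planned fallback. The test of the 36 lists on its z values and the trend removals were chosen after the result was seen.

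The change at 5 days differed from that at 10 days for 1887 of 18120 genes (z test, BH adjusted p under 0.05), and for 1257 with a t distribution. The clearest were Pim2, with a log2 fold 2.36 higher at 5 days than at 10, Pou3f1 (2.23), Kif1a (1.91) and Cldn6 (1.80), and on the other side Inhbb (-2.03) and Cobl (-1.48). All 6 genes had been called at 5 days and none at 10 days. Of the 10 largest rises and 10 largest falls at 5 days, taken among genes with a mean log2 CPM of at least 1 and no predicted-gene name, 19 differed. The exception was the immunoproteasome gene Psmb8 (adjusted p of the difference 0.0911).

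Among the lists, 12 differed between the times by cameraPR on the z values. The adjusted p was 2.48e-26 for formative, 9.39e-17 for naive and 8.45e-05 for 2-cell-like genes. It was 5.81e-09 for p53 targets, 6.77e-05 for Nodal and BMP targets and 0.0126 for imprinted genes. Oxidative phosphorylation had 2.22e-06, genes of the mitochondrial genome 6.77e-05 and DNA replication 0.000343. Lysosome and autophagy (0.0208), ATF4 targets (0.0258) and cholesterol synthesis (0.0346) came last. With a preset correlation of 0.05, 8 of the 12 passed, and imprinted genes (adjusted p = 0.158), lysosome and autophagy (0.182), cholesterol synthesis (0.189) and ATF4 targets (0.196) did not.

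The weak correlation of the 2 times over genes called at 5 days was set against 2 explanations. Spearman's rho of the folds fell from 0.212 to 0.051 (95% bootstrap interval 0.0198 to 0.0857) once length, GC and expression trends were removed at both times. By the limits fixed beforehand that could not tell whether the trends account for it. Cells kept in the pluripotency state of day 5 might also give it. Naive and formative genes had a slope of -0.0103 (-0.06 to 0.03, 38 genes) against 0.07 for 4281 other genes, a test chosen after the result was seen. The interval resamples genes that share the same libraries, and the 0.07 comes from folds with the trends still in them. Naive and formative genes thus kept no detectable slope, but the test cannot exclude that explanation.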

How the results depend on the processing

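The limit of 1 on the log2 fold was planned. All other alternatives below were chosen after the result was seen, since the planned ones need values per library.

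No paired analysis was possible because the tables hold results of comparisons and no values of single libraries. For the same reason count tests (edgeR, DESeq2), RLE scaling, low-count filters, a fit of all 12 libraries, leave-one-out fits, a replicate block, estimated-correlation camera, the rotation test and splits of libraries were not run.

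At 5 days the 2524 higher and 2265 lower genes became 835 and 201 with a log2 fold of at least 1. An adjusted p under 0.01 left 1492 and 1297, and a test against a 1.2-fold change 913 and 363. Removing length and GC trends gave 1993 higher and 2869 lower, a higher share of 41.0% against 52.7%, with 34 falls and 12 rises changing sign, while setting the median to 0 gave 2775 and 1960. The trend removal moved the centre of the folds as well, and the mean z of genes outside the interferon-stimulated list went from 0.054 to -0.228. How much of the turned balance comes from that shift was not tested. At 10 days 0 genes passed with a mean log2 CPM above 0, with the median set to 0 or with trends removed, and the stricter limits could give no more. Genes whose change differed between the times fell from 1887 to 1257 with a t distribution and to 1038 at an adjusted p under 0.01. The share of genes with the same sign at both times moved from 61.8% to 57.6% without length and GC trends and to 53.1% without the expression trend as well.

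With length, GC and expression trends removed 12 lists passed at 5 days in place of 21, 11 of them shared, and 9 at 10 days in place of 16, 7 of them shared. Gained at 10 days were p53 targets (adjusted p = 0.0494) and lysosome and autophagy (0.0203), both higher. Under that setting cytosolic ribosomal proteins turned higher at 5 days (adjusted p = 0.0138), as did genes of the mitochondrial genome (adjusted p = 0.0922). Of named genes, Rpl24 (0.0673), Rps14 (0.0318), mt-Nd3 (0.0402) and mt-Atp6 (0.116) turned to positive log2 folds there, and mt-Atp6 (0.0324) with length and GC trends alone removed. The cause of these moves was not tested.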

Other observations

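The matched lists were planned before their result was seen, while the antigen presentation list, the DMSO levels and the check above a mean log2 CPM of 3 were chosen after the result was seen.

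Of 22 measured genes of antigen presentation 14 rose at 5 days, 0 fell and 8 did not pass (adjusted p over all genes). The list was assembled after these values were seen and was not tested for enrichment, so its direction is not independent evidence. Its median was 0.77, against 0.05 at 10 days. Tap1, a peptide transporter subunit that is also in the p53 list, rose by 1.87 ± 0.16 in the authors' deposited table, Erap1, which trims peptides, by 1.58 ± 0.17, Tapbp by 0.98 ± 0.07 and the proteasome activator gene Psme2 by 0.80 ± 0.07.

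The DMSO controls of the 2 times differed in formative genes, whose level was a median of 0.98 log2 CPM higher in the 5-day control (18 of 19 genes), against 0.02 for 9429 genes above a mean log2 CPM of 3. Naive genes differed by -0.02, with 13 higher and 13 lower. The levels were derived from each gene's mean and fold, with positive read as higher with IAA, and so rest on that reading. They also come from tables normalized separately.

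Falls of gene groups may reflect transcript length and level, so medians were set against 10000 random lists matched on both. At 5 days oxidative phosphorylation (-0.31 against a 95% range of -0.21 to -0.12) and DNA replication (-0.20 against -0.13 to 0.01) lay outside, with 0 and 1 random lists as low. The proteasome (-0.20) lay outside only narrowly, with 204 as low, and cytosolic ribosomal proteins (-0.21 against -0.25 to -0.16) inside, with 3467 as low. At 10 days cytosolic ribosomal proteins (-0.15) and oxidative phosphorylation (-0.16) lay outside, with 17 and 26 as low, yet with length, GC and expression trends removed neither list passed (adjusted p = 0.437 and 0.356), nor did the proteasome at 5 days (0.314), so these 3 are left open. Length and level could account for the 5-day fall of ribosomal protein genes. The 5-day medians of oxidative phosphorylation and DNA replication lay outside the range of matched lists. Both lists also passed at 5 days with length, GC and expression trends removed (adjusted p = 0.0016 and 1.96e-06). Random lists do not keep the way members of a real list vary together, so their ranges may be too narrow. The matched lists therefore cannot exclude length and level for either fall.

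Rises of 1 or more made up 80.6% of such changes at 5 days, which compression of falls near the detection floor might produce. Above a mean log2 CPM of 3 the share was 74.7% (exact 95% interval 66.8 to 81.5, 109 rises and 37 falls). With length and GC trends removed it was 77.6% (74.8 to 80.2, 733 and 212). Both intervals lay above an even split. They treat genes measured in the same 6 libraries as independent, so they do not measure the spread between libraries.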
